A study of Mus musculus with 2 samples.

How the data were processed

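Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed by the authors for EP300, a histone acetyltransferase and transcriptional coactivator, and for histone H3 monomethylated at lysine 4 (H3K4me1), in melan-a cells, an immortal line of mouse melanocytes. Each of the 2 samples represents 2 replicates, per the labels. EP300 was deposited as 2 peak lists, 1 for each replicate, and H3K4me1 as 1 list of regions. Nothing in the labels says that the replicates came from separate cultures, so any spread between them may be technical. Coordinates refer to mm9, per the submitters' processing notes, and are given as deposited. The aligner is not given in the sources used here.

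EP300 peaks were called with MACS 1.4.1 20110627, separately for each replicate against its own control library, per the file headers. The headers give a tag size of 36 bp, an effective genome size of 1.91e+09 bp, a band width of 300 bp, model folds of 10 to 30, a p-value threshold of 1e-05, a fragment size of 200 bp, local background windows of 1000 bp and 10000 bp, and at most 2 duplicate tags per position in the ChIP library. Replicate 1 had 40824757 ChIP tags, of which 31439027 remained after filtering, and 20010848 filtered control tags. Replicate 2 had 43725875 ChIP tags, of which 32355042 remained after filtering, and 24669749 filtered control tags. Per the file headers, each EP300 peak has a count of tags, a significance given as 10 times the -log10 of the Poisson p-value, a fold enrichment of the summit over the local background, and a false discovery rate in percent. The significance values stop at 3100, the highest value in either list. In replicate 1 the strongest 5 peaks are tied there, whereas only 1 peak of replicate 2 has this value.

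For H3K4me1, the deposited list gives for each region a rank, a score by which the regions are ranked (3.00 to 5.28), a maximum log2 fold change, a -log10 Poisson p-value and a false discovery rate (FDR) given as a fraction between 0.000118 and 0.000433. The deposited -log10 values stop at 100, reached by 23426 of the 59923 regions, so regions were ranked by the authors' rank alone. Region edges lie on a grid of 50 bp. The caller, its version, the depth of the H3K4me1 libraries and the way in which the 2 replicates were pooled are not given in the sources used here. All peak values are the authors' and were used to describe, rank or filter peaks within their own list. Values of the 2 EP300 lists were also set against each other at shared loci. Tag counts, significance and fold enrichment further served to work out a background, as described below.

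A shared EP300 locus was the merged interval of overlapping peaks holding at least 1 peak of each replicate, with a minimum overlap of 1 bp. Its centre was the midpoint of the overlap of the best-ranked pair of peaks, and its strength was the mean of the 2 ranks by significance. H3K4me1 was called nearby within 1000 bp of the locus edges. A centre was in a gap when it lay outside any H3K4me1 region with a region within 1000 bp on each side. Overlaps were tested with 10000 random circular shifts of all peaks of a chromosome, within the lowest and highest coordinates of the lists. For clusters, defined as at least 3 shared loci with neighbours within 10 kb, each locus was shifted by its own random distance, which departs from the plan of circular shifts of whole chromosomes, because a common shift leaves clusters as they are. Medians and correlations were tested with 100000 resamples in the main comparisons and 10000 in the alternatives. The smallest p these permutation tests can give is 0.0001 with 10000 draws and 1e-05 with 100000 draws. Chromosomes were compared with exact binomial tests and Benjamini-Hochberg adjustment over 20 chromosomes, leaving out chromosome Y and unplaced sequence. All tests were two-sided. Shares are given with Clopper-Pearson 95% intervals, which cover counting error only. Loci of the same sample are not independent replicates, so the p-values describe these peak lists.

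The control-based background of an EP300 peak was worked out from its tag count and significance by solving the Poisson tail for its mean, over a window of the peak length or 400 bp, whichever was longer, for peaks with a significance under 1000. It is given relative to the genome-wide level, the filtered ChIP tags over the effective genome size. With these values the summit height came out whole to within 0.1 tags for 96.9% of 8403 peaks of replicate 1 and 96.1% of 10317 peaks of replicate 2. For stronger peaks, tags per bp over fold enrichment served as a lower bound on the background. The bound lay at or below the solved value for all but 1 of the same peaks of replicate 1 and for all of those of replicate 2.

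The functions were tested on simulated data before use. With 2000 randomly placed loci, 4% of 100 simulations gave a permutation p under 0.05 for H3K4me1 nearby, and with no planted difference 4.5% of 200 simulations of the median test did. With a planted difference of 10, the median test returned 8.46 on average and gave a permutation p under 0.05 in 55% of 20 simulations. Planted shared loci, clusters and background values were recovered. The background values were simulated with the same Poisson formula that is solved, so their recovery tests the calculation only.

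The tests, alternatives and the rule for the loci named in the text were fixed before the data were examined, apart from the change to the cluster test and the additions named in the closing section. That rule took the 15 shared loci with the best mean rank, the 5 clusters with the most loci, the 5 widest H3K4me1 regions and the strongest 3 peaks of each replicate absent from the other list. The alternatives were an overlap of at least 50% of the shorter peak, the upper 50% of each list, other distances, fold enrichment or tag count in place of significance, random shifts of 20 to 200 kb, chromosome length as yardstick, and all peaks of a single replicate in place of shared loci. Planned tests of distance to transcription start sites, of fixed gene lists and of sequence motifs were not run, because no mm9 genome or annotation was used here. For the same reason no gene is named for any locus. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.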

Results

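Binding of EP300 and the distribution of H3K4me1, a histone mark found at enhancers, were mapped by ChIP-seq in melan-a mouse melanocytes. EP300 was represented by 2 replicate peak lists and H3K4me1 by 1 list for its 2 replicates. The EP300 lists held 8451 peaks in replicate 1, from 31439027 filtered ChIP tags, and 10351 peaks in replicate 2, from 32355042. Median peak lengths were 868 bp and 883 bp, and the median tag count was 43 per peak in each list. The H3K4me1 list held 59923 regions with a median length of 500 bp, which together covered 38.6 Mb. The depth of the H3K4me1 libraries is unknown.

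Fewer than 50% of the EP300 peaks of either list were found in the other, and those that were found tended to be the stronger ones. Of the replicate 1 peaks, 3622 (42.9%, interval 41.8% to 43.9%) overlapped a replicate 2 peak, and of the replicate 2 peaks 3603 (34.8%, interval 33.9% to 35.7%) overlapped a replicate 1 peak. These formed 3573 shared loci with a median length of 1278 bp, and the summits of the 2 replicates lay a median of 67 bp apart. Among the peaks in the top quintile of significance, 91.4% of replicate 1 and 85.4% of replicate 2 were shared, against 10.9% and 7.97% in the lowest quintile. Random circular shifts placed 69.8 replicate 1 peaks on replicate 2 peaks on average, a 51.9-fold difference (permutation p = 0.0001, the smallest possible). The ratio was 26.5 against shifts of 20 to 200 kb, 83.9 with an overlap of at least 50% of the shorter peak, and 122 in the upper 50% of each list.

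Shared peaks had a median fold enrichment of 7.29 in replicate 1 and 6.82 in replicate 2, compared with 5.46 and 5.25 for peaks found in a single list. Their median percentile rank by significance was 75.7 against 32.7 in replicate 1 and 79.5 against 35.98 in replicate 2, with a permutation p of 1e-05 in each list, the smallest possible. Across the 3573 shared loci, which are not independent replicates, the significance values of the replicates correlated with a Spearman rho of 0.608 and a Pearson r of 0.688 on the log10 scale (permutation p = 1e-05 for each, the smallest possible). The median log2 ratio of fold enrichment, replicate 1 over replicate 2, was 0.10 (SD 0.53 across loci). The 5 loci with the highest log2 ratios, a group chosen after the values were seen, had ratios of 1.83 to 3.85, and the next locus had 1.72, close to the lowest of them. The most extreme ratio in the other direction was -1.71. In tags, replicate 1 had at least 8.37 times those of replicate 2 at each of the 5 loci, against at most 3.09 times at any other shared locus, while the highest ratio of replicate 2 over replicate 1 was 4.43 times.

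**Figure D1:**
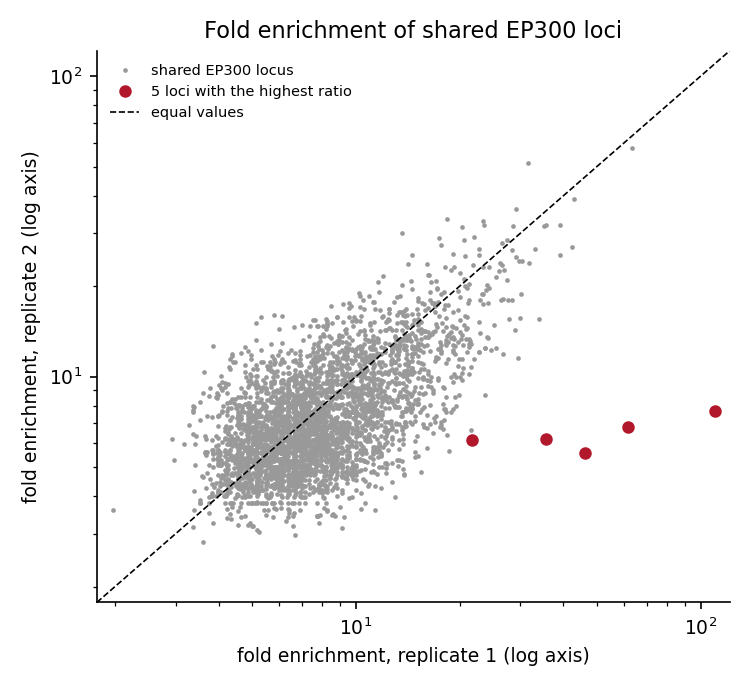
Fold enrichment of the 3573 shared EP300 loci in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), with each point a locus and the dashed line marking equal values. The 5 loci in red had 21.8-fold to 110-fold enrichment in replicate 1 and 5.56-fold to 7.67-fold in replicate 2.

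The 15 shared loci with the best mean rank were 20.6-fold to 63.2-fold enriched in replicate 1 and 18.02-fold to 57.5-fold in replicate 2, and 14 of them had H3K4me1 within 1000 bp. The exception was the best-ranked locus of all, at chromosome 13, 23851908 to 23854039 (mm9), with 63.2-fold and 57.5-fold enrichment. The nearest H3K4me1 region lay 1061 bp from its edge and ranked 50965 among 59923 regions. Next came chromosome 14, 118450921 to 118452798, with 42.8-fold and 38.9-fold enrichment, which overlapped an H3K4me1 region of 4350 bp. The locus at chromosome 6, 137465859 to 137469548, was the longest of the 15 at 3690 bp, with 27.5-fold and 28.4-fold enrichment. On chromosome 2, the loci at 45211638 to 45213643 (42.2-fold and 27.0-fold) and 44077142 to 44079175 (39.2-fold and 32-fold) both ranked among the first 6. The centre of the latter lay in an H3K4me1 gap of 1300 bp. On chromosome 15, the loci at 93359836 to 93361846 (35.6-fold and 31.9-fold) and 63447436 to 63449557 (31.6-fold and 51.3-fold) had centres in H3K4me1 gaps of 1100 bp and 750 bp. So did those at chromosome 5, 58534508 to 58536476, chromosome 12, 103299051 to 103301019, chromosome 3, 79806574 to 79808137, chromosome 14, 70501291 to 70502972, and chromosome 7, 94655110 to 94658068, with gaps of 650 bp to 1100 bp. The remaining loci of the 15 were at chromosome 10, 38272754 to 38274387 and 10188273 to 10190992, and chromosome 4, 80465062 to 80466819.

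Some peaks well up each list were absent from the other list. In replicate 1 the strongest 3 were at chromosome 3, 57366372 to 57367519 (13.97-fold), chromosome 4, 95582105 to 95583287 (8.51-fold), and chromosome 5, 36856637 to 36857351 (13.4-fold), and each of them overlapped an H3K4me1 region. In replicate 2 they were at chromosome 1, 81855594 to 81857280 (9.64-fold), chromosome X, 22642453 to 22643434 (18.3-fold), and chromosome 6, 82954023 to 82956877 (7.79-fold). The peak on chromosome X lay 6404 bp from the nearest H3K4me1 region, whereas the other two overlapped a region. The strongest single-list peak ranked 406 by significance in replicate 1 and 240 in replicate 2.

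Nearly all shared EP300 loci lay beside H3K4me1. A region was found within 1000 bp of 3432 of the 3573 loci (96.1%, interval 95.4% to 96.7%), and 3237 (90.6%) overlapped a region directly. Random circular shifts gave 249 loci (6.96%), so that the observed number was 13.8-fold higher (permutation p = 0.0001, the smallest possible). The 141 loci without H3K4me1 nearby made up 3.95%. The ratio was 5.63 against shifts of 20 to 200 kb, where 17.1% of loci met a region, 21.7 for direct overlap and 6.496 within 5000 bp. The share was lower over all peaks of a single list, at 63.5% without replicate 1 and 67.6% without replicate 2.

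H3K4me1 flanked the EP300 centre on both sides more often than it covered it. The centre of 2226 shared loci (62.3%, interval 60.7% to 63.9%) lay in a gap between 2 H3K4me1 regions, each within 1000 bp, against 16.9 loci under random shifts (permutation p = 0.0001, the smallest possible). The gaps had a median width of 650 bp, with quartiles at 500 bp and 850 bp. Only 437 centres (12.2%) were inside a region, which was still 7.74-fold more than the 56.4 of random shifts (permutation p = 0.0001, the smallest possible). A further 679 loci (19.0%) had a region on a single side of the centre and 231 (6.47%) had none within 1000 bp of it. At 650 bp on either side of the centre, 67.9% and 68.4% of loci were inside a region. The excess in gaps, 132-fold over random shifts, was 48.2-fold against shifts of 20 to 200 kb, 73.0-fold with regions within 2000 bp and 227-fold with the upper 50% of H3K4me1 regions. The share in gaps fell to 42.7% with those upper 50% of regions and to 41.8% with regions within 500 bp. It was 65.5-fold for all replicate 2 peaks (without replicate 1), of which 30.9% had their centre in a gap, and 76.6-fold for all replicate 1 peaks (without replicate 2), of which 36.2% did. The excess inside regions was 2.84-fold against shifts of 20 to 200 kb.

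**Figure D2:**
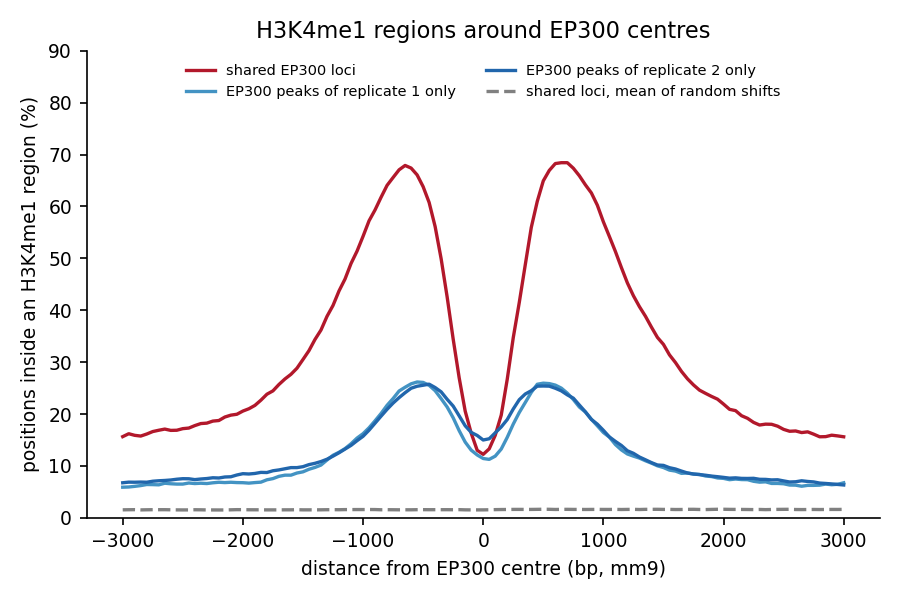
Percentage of positions inside an H3K4me1 region (vertical axis) at each distance in bp from the EP300 centre (horizontal axis, mm9), for shared loci, for peaks found in a single replicate, and for shared loci after random circular shifts. The shared loci rose to 67.9% and 68.4% at 650 bp on either side and fell to 12.2% at the centre.

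Stronger EP300 loci carried H3K4me1 more often. From the lowest to the top quintile of EP300 rank, the share of shared loci with H3K4me1 within 1000 bp was 92.3%, 96.2%, 95.9%, 97.5% and 98.3%. The share with the centre in an H3K4me1 gap went from 52.0% (interval 48.3% to 55.7%) to 72.2% (interval 68.7% to 75.4%). Loci with H3K4me1 had a median percentile rank of 50.8, against 32.3 for the 141 loci without, a difference of 18.5 (permutation p = 1e-05, the smallest possible). Over all peaks of a single replicate the difference was larger, at 38.4 without replicate 1 and 38.6 without replicate 2. H3K4me1 nearby was measured from the locus edges, so a longer locus has more room to meet a region. The 15 best-ranked loci were 1564 bp to 3690 bp long, against a median of 1278 bp for all shared loci. Length was not corrected for, whereas gaps were measured from the centre.

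**Figure D3:**
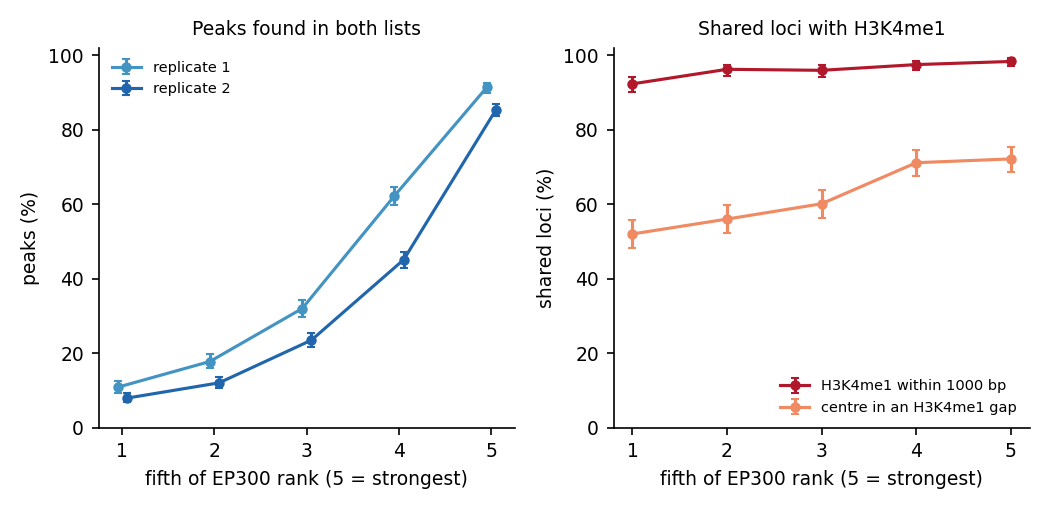
Left, the percentage of EP300 peaks of each replicate found in both lists, and right, the percentage of shared EP300 loci with H3K4me1 within 1000 bp or with the centre in an H3K4me1 gap, by quintile of EP300 rank (horizontal axes, 5 the strongest). Bars are Clopper-Pearson 95% intervals, and each series ends higher in the top quintile than in the lowest.

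H3K4me1 regions that overlapped a shared EP300 locus were wider and ranked higher than the others. There were 5409 such regions, 9.03% of the list, with a median width of 850 bp against 450 bp for the 54514 without EP300, a ratio of 1.89 (permutation p = 1e-05, the smallest possible). Their median percentile rank was 79.5 against 47.1 (permutation p = 1e-05, the smallest possible). EP300 overlapped 22.2% (interval 21.4% to 22.9%) of regions in the top quintile of H3K4me1 rank and 2.34% (interval 2.08% to 2.63%) in the lowest. Wide regions are met more often by chance, so both values were also compared with randomly shifted loci, which met regions with a mean of medians of 586 bp in width (ratio 1.45) and 58.1 in percentile rank (permutation p = 0.0001 for each, the smallest possible). The quintile shares are not corrected for this.

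Of the 5 widest H3K4me1 regions, 3 overlapped a shared EP300 locus. The widest, at chromosome 2, 102714450 to 102723849 (9400 bp), overlapped none but lay 48 bp from the shared locus at 102712634 to 102714402 (18.9-fold and 22.7-fold). The third in width, at chromosome 1, 78143000 to 78151099 (8100 bp), had none within 1000 bp. Those at chromosome 1, 36685800 to 36694849 (9050 bp) and 78156650 to 78164549 (7900 bp) each overlapped 1 shared locus, and the region at chromosome 2, 38383750 to 38391399 (7650 bp), overlapped 2.

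Shared EP300 loci were unevenly spread over chromosomes relative to H3K4me1 regions. Of the 20 chromosomes, 4 had a higher and 3 a lower share of EP300 loci than of H3K4me1 regions after adjustment of exact binomial tests. These tests take each locus as independent and the H3K4me1 share as fixed. Because shared loci also clustered, their p-values may be too small and their intervals too narrow. Chromosome X held 26 loci, 0.278 times its share of regions (interval 0.182 to 0.406, exact binomial adjusted p = 2.72e-15), and chromosome 11 held 182, or 0.711 times (interval 0.614 to 0.819, exact binomial adjusted p = 6.58e-06). Chromosome 6 held 236 loci, 1.31 times its share (interval 1.16 to 1.49, exact binomial adjusted p = 0.000228). Chromosomes 18 (1.26 times), 3 (1.19 times) and 10 (1.18 times, exact binomial adjusted p = 0.0485) were also higher, and chromosome 7 (0.818 times) lower. The background that MACS took from the control was also highest at peaks on chromosome 6, with medians of 1.24 and 1.29 times the genome-wide level in the 2 lists, against at most 1.15 and 1.08 times on any other autosome. With chromosome length as yardstick, X was the only one of these 7 that still passed, at 0.115 times. Chromosomes 15 (1.39 times), 9 (1.26 times) and 14 (0.797 times) passed instead. Chromosome 6 was then at 1.17 times (exact binomial adjusted p = 0.0677) and chromosome 11 turned to 1.10 times (exact binomial adjusted p = 0.303). In the upper 50% of each list 3 chromosomes passed, namely 6, 11 and X.

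**Figure D4:**
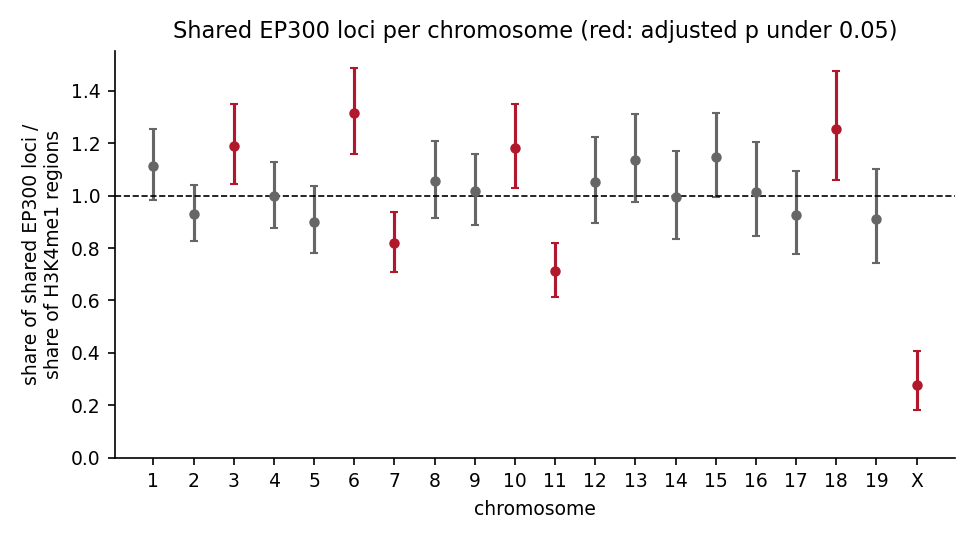
Share of shared EP300 loci divided by the share of H3K4me1 regions (vertical axis) on each chromosome (horizontal axis), with exact 95% intervals as bars and the dashed line at equal shares. Red marks the 7 chromosomes with an adjusted p under 0.05, from chromosome X at 0.278 to chromosome 6 at 1.31.

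Shared EP300 loci gathered in clusters. There were 68 groups of at least 3 loci with neighbours within 10 kb, holding 219 loci (6.13%), against 1.006 groups when each locus was shifted at random (permutation p = 0.0001, the smallest possible), a 67.6-fold excess. Loci were counted apart however close they lay, so a broad enriched stretch split by the peak caller could count as a cluster. Random placement of single loci does not reproduce such splitting, and its part in the excess was not tested. The 3 largest clusters had 5 loci each and lay at chromosome 8, 129349159 to 129377278, with 11 H3K4me1 regions, at chromosome 15, 78985812 to 79007088, with 7, and at chromosome 3, 79700950 to 79724248, with 13. The cluster on chromosome 15 contains 3 of the 5 loci whose enrichment was far higher in replicate 1. The next in order, with 4 loci each, were at chromosome 4, 99158034 to 99190501, and chromosome 15, 79022936 to 79040551, with up to 15.2-fold and 19.7-fold enrichment in replicate 1 and 16.1-fold and 19.3-fold in replicate 2. The excess of clusters was 5.48-fold against shifts of 20 to 200 kb and 37.2-fold with neighbours within 20 kb. It was 12.4-fold without replicate 1 and 15.2-fold without replicate 2, where all peaks of the other list took the place of shared loci.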

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

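Outside the comparison of chromosomes, all 62 alternatives, of which 8 were added, left each result in its direction and past its threshold: EP300 overlap, strength and correlation, H3K4me1 nearby, in gaps and inside regions, H3K4me1 width and rank, and clusters. The alternatives without chromosome 6, without the 5 loci far stronger in replicate 1, with MACS summits as centre and with the top quintile of shared loci for chromosomes were chosen after the data were seen. Ratios over random placement that moved by over 1.5 times are given with each result. Past the threshold were 7 chromosomes, but 4 with chromosome length as yardstick (X of the 7, and newly 9, 14 and 15), 3 in the upper 50% of each EP300 list (6, 11 and X) and 4 in the top quintile of shared loci (10, 11 and X of the 7, and newly 5 at 0.619 times), the last 2 with fewer loci. It was 10 without EP300 replicate 1 and 9 without EP300 replicate 2. Chromosome 11 reversed to 1.10 times its share with chromosome length as yardstick, since it holds 7.16% of H3K4me1 regions and 4.61% of the summed length. Chromosome 6 lost its call with chromosome length (1.17 times) and in the top quintile (1.39 times), where its ratio was not lower. Chromosomes 3, 7, 10 and 18 lost theirs with chromosome length (1.04, 0.910, 1.15 and 1.16 times) and in the upper 50% of each list, where their ratios stayed close to the main ones (1.20, 0.843, 1.16 and 1.20 times), and 3, 7 and 18 also in the top quintile (1.35, 0.739 and 1.23 times). For chromosome length the cause was not tested further. Chromosome X was low in all of these alternatives. The planned tests of start sites, gene lists and motifs were not run. Intervals cover counting error, and the depth behind the H3K4me1 list is unknown, so absence of a region is not absence of the mark.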

Other observations

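The comparisons of single-list peaks, of cluster strength and of chromosomes between lists, and the tests on chromosomes and on the 5 loci stronger in replicate 1, were chosen after the results were seen. For the tests on H3K4me1 gaps, the outcome that would count against each explanation was set before its result was seen.

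EP300 peaks found in a single list had H3K4me1 nearby less often than shared peaks, but more often than by chance. Of the 4829 peaks found in replicate 1 alone, 2249 (46.6%, interval 45.2% to 47.99%) had H3K4me1 within 1000 bp, and of the 6748 in replicate 2 alone 3114 (46.1%, interval 44.95% to 47.3%), against 95.6% and 95.9% of the shared peaks of each list (odds ratios 25.2 and 27.2) and 6.14% and 6.19% of single-list peaks under random shifts (permutation p = 0.0001 in each, the smallest possible). Their centres lay in an H3K4me1 gap in 18.8% and 16.2% of cases, against 0.469% and 0.468% under random shifts, and inside a region in 11.4% and 14.997% of cases, 7.27-fold and 9.54-fold more than under random shifts. In replicate 2 the share inside a region was thus close to that in a gap. Seen from H3K4me1, 24595 gaps of at most 2000 bp separated neighbouring regions, and 2375 of them (9.66%) held the centre of a shared locus. The 219 shared loci in clusters had a median percentile rank of 63.5 against 49.3 for other shared loci (permutation p = 0.0001, the smallest possible), and 98.2% of them had H3K4me1 nearby against 95.9%.

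After the best-ranked locus, the strongest shared loci without H3K4me1 within 1000 bp were at chromosome 1, 193398623 to 193399904 (23.9-fold and 19.4-fold enrichment), and chromosome 13, 28509038 to 28510464 (12.9-fold and 12.7-fold). The locus with the most tags, at chromosome 17, 39979456 to 39986263, had 7284 tags but 1.97-fold enrichment in replicate 1 and 7916 tags with 3.61-fold enrichment in replicate 2, over a background of at least 33.8 and 19.0 times the genome-wide level. By significance it ranked 3190 in replicate 1 but 1 in replicate 2, where it was the only peak at 3100. Chromosome 18 held 4.14% of replicate 1 peaks and 4.80% of replicate 2 peaks (odds ratio 1.17, Fisher's exact p = 0.0311), which failed Benjamini-Hochberg adjustment over 20 chromosomes (adjusted p = 0.621).

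Chromosome 6 held 1.31 times its share among shared loci, and 3.19 times (interval 2.92 to 3.49) and 2.96 times (interval 2.73 to 3.20) among single-list peaks of replicates 1 and 2 without H3K4me1 nearby, but 1.49 times (interval 1.28 to 1.72) and 1.36 times (interval 1.18 to 1.54) among single-list peaks with H3K4me1 nearby. Stronger EP300 binding along chromosome 6 stays open: the ratio was 1.39 (interval 1.04 to 1.81) in the top quintile of shared loci, and a rise in signal from either more binding or more copies could bring further sites over the peak threshold. As a hypothesis, with copy number not measured and read mapping not tested, extra copies of chromosome 6 may account for the excess. The median control-based background at its single-list peaks without H3K4me1 was 1.09 and 1.16 times the genome-wide level. The medians of all other autosomes lay at that level, as did 41.5% and 34.5% of all solved values, the lowest of which were 0.598 and 0.793 times it. The level acts nearly as a floor for the solved values, so control densities below it cannot be read from them. The other autosomes are therefore not shown to have equal control densities. On chromosome 6, 69.8% and 80.9% of these single-list peaks were above the level. The next highest was chromosome 18, with 36.4% and 49.2% above the level and 1.47 and 2.04 times its share of H3K4me1 regions among the same kind of peaks. Likewise, fewer copies of chromosome X could account for its deficit, since 7.84% of its 51 peaks in replicate 1 and 13.1% of 61 in replicate 2 had a background above the genome-wide level, against at least 48.95% on each autosome. Control densities on chromosome X below that level cannot be read from these values. Copy number would bear on H3K4me1 as well, and a separate effect on EP300 was not tested. Chromosome 6 held 5.02% of H3K4me1 regions and 5.67% of the summed length, so H3K4me1 showed no surplus there. Chromosome X held 2.62% and 6.31%, so its deficit is relative to an H3K4me1 share that is itself low.

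The 5 shared loci far stronger in replicate 1 were at chromosome 15, 78985812 to 78987364, 78989191 to 78990279 and 78993337 to 78995185, chromosome 12, 86814315 to 86815508, and chromosome X, 103381762 to 103382866. A difference in sequencing depth is argued against, because replicate 1 had 0.972 times the filtered tags of replicate 2 and at least 8.37 times the tags at each of the 5 loci. For the 3 loci on chromosome 15, DNA in the replicate 1 preparation other than immunoprecipitated chromatin is a candidate explanation, since the background from the control of replicate 1 was at least 1.86 times the genome-wide level at each, against at most 1.15 times in replicate 2. A local gain of copies in the replicate 1 cells would raise the control as well and was not tested apart from it. By itself, such a gain would raise ChIP and control tags alike. Enrichment over the local background was 21.8-fold to 46.2-fold at the 3 loci in replicate 1, against 5.56-fold to 6.21-fold in replicate 2. These values argue against a gain of copies as the only cause there. Extra DNA present alike in the ChIP and control libraries would meet the same objection. The amount of such DNA in each library was not measured, so the values do not tell the 2 explanations apart. For the loci on chromosomes 12 and X the bound reached only 0.355, below the genome-wide level. That leaves extra DNA in the replicate 1 preparation undecided there, because no upper bound could be had.

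The position of EP300 in H3K4me1 gaps was set against chance fragmentation of the H3K4me1 regions. When regions were joined over gaps of at most 2000 bp, 2812 shared loci had their centre in such an island, and 84.5% of these centres lay in a gap, whereas centres placed at random in the same islands did so in 32.5% of cases on average and at most 35.8% in 10000 draws. Random breaks made by the caller are thereby argued against as the cause. Across the 2226 loci in gaps, stronger EP300 went with wider gaps, with a Spearman rho of 0.160 (permutation p = 1e-05, the smallest possible) and median widths of 550 bp in the lowest and 700 bp in the top quintile. Displacement of nucleosomes at EP300 sites is a candidate explanation that these lists could not test, since they hold no signal between regions.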
